A study of Homo sapiens with 9 samples.

How the data were processed

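RNA from pools of 8 to 12 cortical organoids at day 28, differentiated from clones of the H9 embryonic stem cell line, was sequenced as paired-end reads from a NEBNext Ultra library. The submitters' processing notes name Trimmomatic, HISAT2, featureCounts, DESeq2 and deepTools and the genome build hg38, with no versions and no settings. The deposited raw counts are whole numbers of reads per gene and library from alignment files, made by the authors without any scaling that the values show. The deposited normalised signal equals the raw count divided by a constant for each library, as checked on all genes, and was used for that check alone. The annotation release, the strand setting and the handling of reads that map to several places are not stated.

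The table holds 58288 genes under versioned Ensembl identifiers. Names and positions came from GENCODE 29 (GRCh38, the same build) joined on the identifier without its version, which matched 58025 genes, 55619 of them also with the version. The 263 others kept no symbol. The 45 entries of the pseudoautosomal regions of Y, with 994 counts in all, were left out. Groups, clones and replicate numbers were taken from the sample titles. For the Het library the title gives replicate 2 and its description 1, and the title was followed. The libraries held 13184007 to 16231276 counts, and 3 counts in a library correspond to about 0.2 CPM, which was taken as the floor for genes at 0. Floors cover counting error only, since the reads carry no molecular identifiers.

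Tests were run on the raw counts in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr on the genotype groups, which kept 18256, and scaled with TMM. KO against WT was tested with edgeR's quasi-likelihood test over the 8 libraries without other terms, and genes at an adjusted p (Benjamini-Hochberg) of at most 0.05 were called. Because libraries are nested in 2 clones per genotype, the same test was run on counts summed per clone. Single clones were compared in a fit with clone as the factor, whose spread is that between pools of a clone: F5 against WT, B1 against WT, F5 against B1 and G5 against E5. SEs of log2 fold changes were derived from edgeR's F statistic. CPM values are TMM scaled, and log2 CPM used a prior count of 2. Clone means of ZNF675 and HES1 were compared with an exact two-sided permutation test, whose smallest p with 2 against 2 clones is 0.333. The Het library was not tested, having no replicate.

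The comparisons, gene lists, alternatives and the rule for named genes were set before the data were examined. The 24 lists are the Notch pathway and HES/HEY, dorsal forebrain radial glia, neurogenic and intermediate progenitors, postmitotic neurons, ventral telencephalon and hypothalamus, cortical hem and choroid plexus, midbrain, hindbrain and spinal cord, retina and pigment epithelium, neural crest and mesenchyme, non-neural epithelium, pluripotency, endoderm, muscle and endothelium, astroglia and oligodendrocyte lineage, G1/S and G2/M cell cycle, hypoxia and glycolysis, integrated stress and unfolded protein response, p53 targets, WNT/beta-catenin targets, BMP and TGF-beta targets, hedgehog targets, the KRAB zinc finger cluster around ZNF675, immediate early genes and mitochondrially encoded proteins. They were tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation, with camera on ranks and with fry, each adjusted over the lists, and their members also by edgeR p adjusted over the list alone. The list tests on single clones were chosen after the data were seen. Named were ZNF675 and HES1, of KO against WT up to 12 genes with the highest and 12 with the lowest log2 fold change among those called with a symbol, a mean log2 CPM of at least 1 and clone means apart, up to 4 members with the smallest p of each list described, and the 3 highest and 3 lowest of each comparison of single clones. For the list members named in the tests on single clones, the same 4 were used, except that FEZF2, DMRT3, DMRTA2, EMX1, EMX2, TBR1 and BOC in F5 were chosen after the data were seen.

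The alternatives set in advance were DESeq2's size factors, the DESeq2 Wald test, limma-voom, no filter beyond 1 read, a CPM above 1 in at least 4 libraries, counts summed per clone, limma-voom with clone as a random block (consensus correlation 0.663), the replicate number as a block, the Het library in the fit, a log2 fold change of at least 1, leaving out each library and leaving out each clone. Offsets per library for GC content and exonic length (natural splines with 5 degrees of freedom), alone and with counts summed per clone, and leaving out the genes of chromosome 12 were chosen after seeing the data. Distances between libraries were SDs of log2 CPM differences over 14809 genes with a mean log2 CPM of at least 1. The figures were drawn with matplotlib.

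The methods were tested on simulated data. With 200 changed genes the KO against WT test over 8 libraries recovered 63% at a log2 fold change of 1 and 94% at 2, with 12 false among 169 calls. Here every library was drawn independently, with no level shared by the libraries of a clone. These values therefore do not give the recovery or the false calls for libraries nested in clones. With clones that differ but no genotype difference, 10 simulations gave a median of 428.5 calls over libraries and 0 over clone sums, with 17.4% and 5.18% of genes at an unadjusted p under 0.05. The overlap of F5 and B1 was simulated in the same way, with the SD between the clones of a genotype as the spread of all clones. A simulated GC trend, put on otherwise unchanged counts, gave 5533 calls without and 0 with the offsets. It cannot show what the offsets do to real differences that go with GC content. A list shifted in simulation was called by camera at the preset correlation (adjusted p = 4.06e-34) with 0 of the unshifted lists. These lists held random genes and the clones did not differ. False calls for lists of genes that vary together between clones were therefore not tested.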

Results

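The series holds 9 RNA sequencing libraries from cortical organoids at day 28. Cortical organoids are cell aggregates that are differentiated in suspension towards cells of the dorsal forebrain, and these came from H9, an established human embryonic stem cell line. The line had been transfected with CRISPR-Cas9 constructs aimed at ZNF675, a KRAB zinc finger gene, and expanded as single clones. The labels give 2 wild-type (WT) clones, E5 and G5, 2 clones labelled knockout (KO), B1 and F5, each with 2 libraries, and 1 library of a clone labelled heterozygous (Het), G10. Each library was made from a pool of 8 to 12 organoids. Clones, not pools, are the independent units of the genotype, and the design has 2 against 2 of them. The total counts per library were 15010635 and 14667502 in E5, 13460681 and 15941046 in G5, 16231276 and 13701454 in B1, 13184007 and 13839011 in F5, and 15613456 in the Het library.

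The first question was how much RNA of the edited gene itself was present. ZNF675 (ENSG00000197372.9, GRCh38 chromosome 19, 23525631 to 23687220) had 28.4 ± 3.95 CPM (counts scaled to library size, SD, n = 4) in WT and 55.7 ± 8.70 (n = 4) in the libraries labelled KO. The means of the clones were 31.0 CPM in E5, 25.8 in G5, 48.4 in B1 and 63.0 in F5, and the Het library had 32.9 CPM. Its RNA was thus higher, not lower, in all 4 libraries labelled KO than in all 4 WT libraries, with a log2 fold change of 0.97 (SE 0.15). Against the spread between pools of a clone, ZNF675 was higher than in WT both in F5 (1.16, adjusted p = 4.68e-06) and in B1 (0.78, adjusted p = 0.00142). Over the libraries the KO against WT difference had an adjusted p of 0.0860 with edgeR, and it passed the threshold with DESeq2 (adjusted p = 1.88e-05) and with offsets for GC content and length (0.88, adjusted p = 0.0123). An exact two-sided permutation test of the 4 clone means gave p = 0.333, the smallest that 2 against 2 clones can give. The position and size of the edits are not given with the data, and counts per gene cannot show a small insertion or deletion, so the labels KO and Het could not be checked against the RNA.

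HES1, a transcriptional repressor downstream of Notch that keeps neural progenitors undifferentiated, is the gene in the title of the series. HES1 (ENSG00000114315.3, chromosome 3, 194136145 to 194138732) had 114 ± 33.5 CPM in WT and 59.3 ± 41.8 in the libraries labelled KO (SD, n = 4 each), a log2 fold change of -0.94 (SE 0.49, edgeR adjusted p = 0.420). The clones labelled KO differed from each other: F5 had 18.1 and 28.4 CPM, below every WT library, and B1 had 95.9 and 94.7 CPM, between the WT clones E5 (85.1 on average) and G5 (142). HES1 was 0.212 times its WT level in F5 (log2 fold change -2.24, SE 0.15, adjusted p = 4.16e-07), while B1 had a log2 fold change of -0.21 (adjusted p = 0.450). The difference between F5 and B1 passed its own test (-2.03, adjusted p = 5.10e-06), and so did that between the WT clones G5 and E5 (0.74, adjusted p = 0.00291). The exact two-sided permutation test of the 4 clone means gave p = 0.667, and the Het library had 111 CPM. Without clone B1 the KO against WT difference was -2.29 (adjusted p = 0.00705), and without clone F5 it was -0.24 (adjusted p = 0.979).

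**Figure D1:**
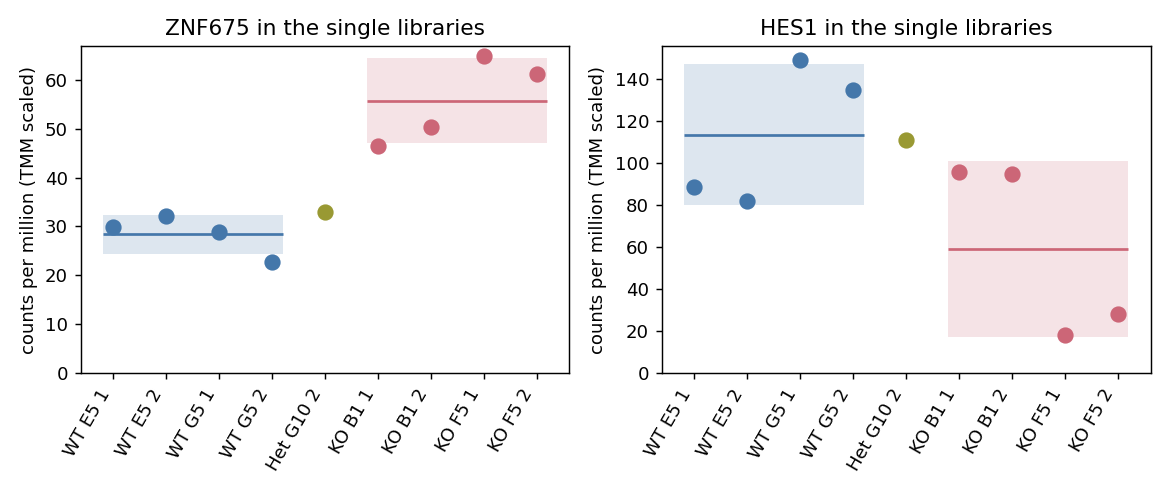
ZNF675 (left) and HES1 (right) in the single libraries, in TMM-scaled CPM on the vertical axes; each point is a library, the lines are the means and the shaded bands the SD of the 4 WT (blue) and the 4 KO (red) libraries, and the Het library is the olive point. ZNF675 lies between 46.5 and 64.8 CPM in the KO libraries and between 22.9 and 32.1 in WT; HES1 is low in F5 (18.1 and 28.4) and not in B1 (95.9 and 94.7).

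The comparison of the libraries labelled KO with WT asked which genes differ with the ZNF675 genotype. SLC5A12, a sodium-coupled transporter of lactate and other monocarboxylates, fell from 5.45 ± 1.88 CPM in WT to 0.760 ± 0.0240 in the libraries labelled KO (SD, n = 4 each; log2 fold change -2.83, SE 0.29, adjusted p = 0.0226). SLC5A12 (ENSG00000148942.14, chromosome 11, 26667019 to 26723427) was as low in B1 (0.758 CPM) as in F5 (0.761), and the Het library had 1.34. In all, 2 genes passed as lower and 0 as higher among 18256 genes tested with edgeR over libraries. The other one lay at a level below the minimum for named genes. An unadjusted p under 0.05 was reached by 2581 genes (14.1%). Simulated clones that differed without a genotype difference gave a median of 17.4% in the same test. The share of 14.1% therefore does not by itself point to the genotype. On counts summed per clone 0 genes passed, with 674 (3.69%) at an unadjusted p under 0.05, limma-voom gave 0 and DESeq2 614 (317 higher, 297 lower). Leaving out a library left 0 genes for 7 of the 8 libraries and 1 gene, SLC5A12, without E5 replicate 2. Without a clone the count was 482 (E5), 11 (G5), 1738 (B1) or 4 (F5), with offsets for GC content and length it was 201, and without a filter on low counts 209.

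**Figure D2:**
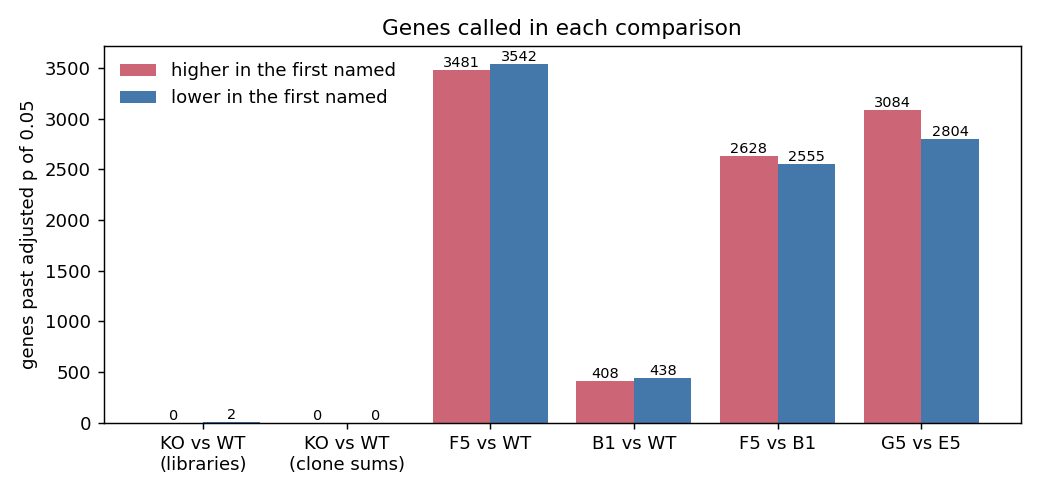
Number of genes past an adjusted p of 0.05 (vertical axis) in each comparison (horizontal axis), higher (red) or lower (blue) in the first named, out of 18256 genes tested with edgeR. KO against WT has 2 genes over libraries and 0 over clone sums, while F5 against WT has 7023, F5 against B1 5183 and the WT clones G5 against E5 5888.

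Of the gene lists written for this tissue, the integrated stress and unfolded protein response had the smallest p, and it was lower in the libraries labelled KO. PSAT1, an enzyme of serine synthesis, had 246 ± 22.2 CPM in WT and 158 ± 3.16 in the libraries labelled KO (log2 fold change -0.64, SE 0.10, adjusted p = 0.0860). XBP1, a transcription factor of the unfolded protein response, had 53.1 and 31.5 CPM (-0.75). DDIT3, the stress-induced factor CHOP, had 10.8 and 6.01 CPM (-0.84). It overlaps MARS on the opposite strand, which had 293 CPM in WT and a log2 fold change of -0.90 (adjusted p = 0.165), and the strand setting of the counting is not known. CHAC1, a glutathione-degrading target of ATF4, had 25.5 and 10.8 CPM (-1.23). Of the 15 members, 12 were lower and 0 higher when adjusted over the list alone, and 0 passed over all genes tested. Both clone means labelled KO lay below both WT clone means for 13 of the 15, where chance gives 16.7% for a single gene. The members were measured in the same clones and may vary together, so they are not 15 independent trials. Over all genes tested, 28.3% had clone means apart in either direction. Of the 15, 11 were lower than in WT in F5 and 11 in B1. The list fell with camera (adjusted p = 6.65e-11, median log2 fold change -0.72) and with fry (adjusted p = 0.00216), and it had adjusted p = 0.106 with an estimated correlation. These tests, and those of the lists below over libraries, took libraries and not clones as the units. Pools of a clone thus counted as replicates, and the p-values can be too small for the genotype. On counts summed per clone camera, again at the preset correlation, gave an adjusted p of 1.13e-08. That value sets the list against the other genes and is not a test with clones as the units.

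The list of hypoxia and glycolysis genes fell as well (camera adjusted p = 0.000855, fry 0.0241), with adjusted p = 0.298 with an estimated correlation. Among its 18 tested members 6 were lower and 1 higher adjusted over the list alone, and 0 over all genes tested. ALDOC, a glycolytic aldolase, had 13.8 CPM in WT and 5.41 in the libraries labelled KO (-1.34). LDHA, lactate dehydrogenase, had 59.9 and 31.8 CPM (-0.91), and VEGFA, a hypoxia-induced growth factor, had 148 and 84.6 CPM (-0.81).

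Genes of neurons and of the ventral forebrain were the 2 lists that rose in the libraries labelled KO. NSG2, a neuronal endosomal protein, had 233 ± 28.5 CPM in WT and 394 ± 44.1 in the libraries labelled KO (0.76). DCX, a microtubule protein of migrating neurons, had log2 fold changes of 1.21 in F5 (adjusted p = 2.36e-07) and 0.42 in B1 (adjusted p = 0.00776). INA and STMN4, cytoskeletal proteins of neurons, had log2 fold changes of 0.61 and 0.37. Of the 26 postmitotic neuron genes, 10 were higher and 2 lower adjusted over the list alone, and 0 over all genes tested (camera adjusted p = 0.0184, and adjusted p = 0.481 with an estimated correlation). In F5 14 were higher and 7 lower than in WT (camera adjusted p = 0.0803, and 0.602 with an estimated correlation). In B1 7 were higher and 0 lower (camera adjusted p = 0.00148, and 0.621 with an estimated correlation). For KO against WT 16 members lay above 0 and 10 below. The camera adjusted p of the list for KO against WT was 0.0523 without E5 replicate 1, 0.0505 without G5 replicate 1, 0.0837 on counts summed per clone and 0.0592 with camera on ranks. GAD2, an enzyme of GABA synthesis, had 47.0 and 119 CPM (1.34), and the homeobox genes of the ganglionic eminences DLX1, GSX2 and DLX6 had log2 fold changes of 1.43, 1.13 and 1.49. DLX6 (9.03 CPM in E5 and 27.1 in G5) overlaps DLX6-AS1 on the opposite strand. DLX6-AS1 had 343 CPM in WT and a log2 fold change of 1.23 (adjusted p = 0.215). Since the strand setting is not known, reads of DLX6-AS1 may be counted in DLX6. Of the 10 tested genes of ventral telencephalon and hypothalamus, 4 were higher adjusted over the list alone and 0 over all genes tested (camera adjusted p = 0.000339, and adjusted p = 0.481 with an estimated correlation). In F5 8 of these 10 were higher than in WT and in B1 2, and 6 were higher in the WT clone G5 than in E5.

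The list of neurogenic and intermediate progenitor genes fell (camera adjusted p = 0.000883, and adjusted p = 0.481 with an estimated correlation). NHLH2, a transcription factor of newborn neurons, had 22.5 CPM in WT and 6.81 in the libraries labelled KO (-1.72). It was the 1 of 15 members that was lower adjusted over the list alone, and 0 passed over all genes tested. NEUROD1 and NEUROD4, proneural factors, had log2 fold changes of -1.41 and -1.73. In F5 10 members were lower and 1 higher than in WT (median -2.45, camera adjusted p = 0.000891, and adjusted p = 0.281 with an estimated correlation). In B1 1 was lower and 0 higher (median -0.30, camera adjusted p = 0.114). The list of 24 Notch pathway and HES/HEY genes fell too (camera adjusted p = 0.000692, and adjusted p = 0.481 with an estimated correlation), but 0 members passed adjusted over the list alone. HES5, a Notch target of neural progenitors, had 60.4 CPM in WT and a log2 fold change of -1.01. HEYL, MFNG and NRARP, other targets or modifiers of Notch, had log2 fold changes of -1.27, -0.96 and -0.54. In F5 13 Notch genes were lower and 1 higher than in WT, in B1 2 were lower and 0 higher, and 11 were higher and 2 lower in the WT clone G5 than in E5.

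The other lists that fell held markers of other tissues or states and WNT target genes. The cortical hem and choroid plexus list (19 tested genes, camera adjusted p = 0.000339, and adjusted p = 0.574 with an estimated correlation) includes RSPO3, an enhancer of WNT signalling. RSPO3 had 42.3 CPM in WT and 10.7 in the libraries labelled KO (-1.97), and 0 members passed adjusted over the list alone. The list of 13 WNT target genes fell (camera adjusted p = 0.00123, and adjusted p = 0.574 with an estimated correlation), again with 0 members adjusted over the list alone. APCDD1, a WNT antagonist, had 17.1 and 9.43 CPM. Of 14 genes of neural crest and mesenchyme, 4 were lower adjusted over the list alone (camera adjusted p = 0.00635, and adjusted p = 0.481 with an estimated correlation). LUM, a matrix proteoglycan, had 1.77 and 0.342 CPM, and COL1A1, a fibrillar collagen, had 3.36 and 1.01. TFAP2B and TFAP2A, factors of crest and surface ectoderm, were high in E5 replicate 2 (78.4 and 45.2 CPM), while all other libraries had at most 3.17 and 3.69. The camera adjusted p of this list was 0.0805 without E5 replicate 1 and 0.105 without E5 replicate 2. The pluripotency list had 3 tested genes, 2 of them lower adjusted over the list alone (camera adjusted p = 0.00429, and adjusted p = 0.481 with an estimated correlation). They were DPPA4 (6.38 and 1.66 CPM) and LIN28A (6.83 and 2.15). The 9 tested genes of retina and pigment epithelium had a camera adjusted p of 0.0391, adjusted p = 0.574 with an estimated correlation and 0 genes adjusted over the list alone. It was 0.166 without E5 replicate 1, 0.155 and 0.0652 without F5 replicate 1 and 2, 0.0575 without G5 replicate 2 and 0.0734 with offsets for GC content and length. PMEL, a melanosome protein, had 1.24 and 0.426 CPM and overlaps CDK2 on the opposite strand. CDK2 had 85.5 CPM in WT and a log2 fold change of -0.76, so its reads may be counted in PMEL. In these lists 0 genes passed over all genes tested. Against WT the medians of the hem, WNT target, retina, crest and pluripotency lists were -3.58, -1.35, -1.33, -1.67 and -2.28 in F5. In B1 they were -0.08, 0.05, 0.34, -0.24 and -0.80. Genes lower in B1 numbered 1, 0, 0, 2 and 1, and genes higher 0, 1, 1, 1 and 0. Of these lists only pluripotency passed in B1 (camera adjusted p = 0.0204, and 0.537 with an estimated correlation).

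In all, 11 of 24 lists passed with the preset correlation (2 higher, 9 lower in the libraries labelled KO), 0 with an estimated correlation (smallest adjusted p = 0.106) and 2 with fry, the stress and the hypoxia list. With camera at the preset correlation on counts summed per clone, and with camera on ranks, the count was also 11, with other members. Both lost the neuron list, and the midbrain list passed on clone sums (0.00971) and G1/S on ranks (0.0240). Without B1 replicate 1 or without B1 replicate 2 it was 17, without clone B1 18 and without clone E5 6. The stress and the hypoxia list passed without each of the 4 clones. Without clone E5 the neurogenic, ventral, hem, retina, crest, pluripotency and WNT target lists did not pass, with adjusted p from 0.0511 (neurogenic) to 0.634 (crest). Without clone F5 the hem, retina, crest and WNT target lists did not pass (0.127 to 0.539), without G5 the Notch (0.231), neuron (0.166) and retina lists (0.0753), and without B1 the neuron list (0.162). The lists that did not pass were dorsal forebrain radial glia (adjusted p = 0.111), midbrain, hindbrain and spinal cord (0.148, 4 genes tested), non-neural epithelium (0.691), endoderm, muscle and endothelium (0.309, 3 genes) and astroglia and oligodendrocyte lineage (0.432). G1/S cell cycle had an adjusted p of 0.0520, G2/M cell cycle 0.815, p53 targets 0.151, BMP and TGF-beta targets 0.250 and hedgehog targets 0.913, the last with a median of -0.09, a mean of 0.01 and a lower call of direction. The KRAB zinc finger cluster around ZNF675 had an adjusted p of 0.123, immediate early genes 0.181 and mitochondrially encoded proteins 0.656. Leaving out a library brought some of these under the threshold. Without B1 replicate 1 and without B1 replicate 2 these were radial glia (0.0257 and 0.0308), p53 targets (0.0222 and 0.0229), the zinc finger cluster (0.0222 and 0.00756) and immediate early genes (0.0457 and 0.0191). The p53 list also passed without G5 replicate 2 (0.0460), endoderm without B1 replicate 2 (0.0218) and mitochondrial genes without E5 replicate 2 (0.0180). The midbrain list passed without any library of F5 (0.0148 and 0.00482), G5 (0.00115 and 0.0259) or B1 (0.0111 and 0.0113). G1/S passed without E5 replicate 1 (0.0484), E5 replicate 2 (0.00247), F5 replicate 2 (0.0445) or B1 replicate 1 (0.0457). Among the radial glia genes, SOX2, which maintains progenitors, had 199 and 144 CPM, NES, an intermediate filament of progenitors, had 558 and 367, and SLC1A3, a glutamate transporter, had 209 and 267.

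Clone F5 stood farthest from WT. WNT8B and WNT3A, ligands of the cortical hem, had 0.635 and 0.112 CPM in F5, against 61.3 and 7.70 in E5 and 22.5 and 5.30 in G5, a log2 fold change of -5.84 (SE 0.70) for WNT8B. CDC20B, a gene of multiciliated cells, had 0.0747 CPM in F5, against 12.5 in E5 and 4.79 in G5. At a floor of 3 counts per library WNT3A and CDC20B were at least 23.2-fold and 21.0-fold lower in F5 than in the lower WT clone. RSPO3 (-3.83) and WNT5A (-3.22) were lower as well, and 15 of the 19 hem and choroid plexus genes were lower than in WT and 0 higher (camera adjusted p = 9.95e-07, and adjusted p = 0.285 with an estimated correlation). Of the 13 WNT target genes 11 were lower in F5, among them ZNRF3 (-1.46), a WNT-induced ubiquitin ligase, and AXIN2 (-0.63), a feedback inhibitor (camera adjusted p = 7.16e-07, and adjusted p = 0.141 with an estimated correlation). OTX1, a homeobox gene of forebrain and eye, was lower in F5 (-2.46), and so were 6 of the 9 retina genes. Factors of the dorsal forebrain were lower too: FEZF2 (-3.35), DMRT3 (-3.42), DMRTA2 (-3.28), EMX2 (-2.93), EMX1 (-2.70) and TBR1 (-2.41). Of the 21 radial glia genes 12 were lower and 4 higher in F5 (camera adjusted p = 0.0108, and adjusted p = 0.451 with an estimated correlation), and in B1 0 were lower and 1 higher (camera adjusted p = 0.997). The ventral genes DLX1 (2.10) and GAD2 (1.86) were higher, as were PTCH1 (0.98), a hedgehog receptor and target, and OLIG1 (2.30), a factor of the oligodendrocyte lineage. Their lists did not rise: of 8 hedgehog targets 2 were higher and 4 lower in F5 (median -0.55, camera adjusted p = 0.402), among the lower BOC (-0.69), and of 8 genes of astroglia and the oligodendrocyte lineage 2 were higher and 3 lower (median -1.14, 0.136). Of 18 p53 targets 13 were lower, with TNFRSF10B, a death receptor, at -1.15 and MDM2, the p53 ligase, at -0.31, and of 14 immediate early genes 9 were lower, with IER2 at 28.8 CPM against 58.0 in WT and NR4A1 at -1.07. Of the 24 tested genes of the zinc finger cluster around ZNF675, 15 were higher and 0 lower (camera adjusted p = 3.75e-05, and adjusted p = 0.308 with an estimated correlation). With offsets for GC content and length the cluster had an adjusted p of 0.0775 in the same direction. In all, 3481 genes were higher and 3542 lower in F5 than in WT (7023 of 18256, 38.5%), and 3919 and 2907 with offsets for GC content and length. Without the offsets 17 lists passed (3 higher, 14 lower), 0 of them with an estimated correlation (smallest adjusted p = 0.141). F5 is a single clone, so this test used the spread between pools. Without F5 replicate 2 the count was 4441.

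Clone B1 was nearer to WT. ZNF558 and ZNF559, zinc finger genes on chromosome 19, had 0 and 0.168 CPM in B1 against 44.5 to 58.1 and 23.4 to 37.2 in the WT clones. For ZNF558 this is at least 224-fold lower than in the lowest of the clones that expressed it, at a floor of 3 counts per library. ZNF404, also of chromosome 19, had 0.0305 CPM in B1 and 2.83 and 5.82 in E5 and G5. Of the 15 stress response genes 11 were lower in B1 and 0 higher (camera adjusted p = 3.93e-12, and adjusted p = 0.445 with an estimated correlation). HES5 was lower in B1 (-1.49, adjusted p = 4.01e-05) and in F5 (-0.59, adjusted p = 0.00155). In F5 HES5 did not pass with offsets for GC content and length (-0.30, adjusted p = 0.0793). Of 18 p53 targets 3 were higher in B1, the opposite direction to F5 (camera adjusted p = 0.00306, and adjusted p = 0.445 with an estimated correlation). In all, 408 genes were higher and 438 lower in B1 than in WT (846, 4.63%), and 348 and 245 (593) without the genes of chromosome 12. With all genes 9 lists passed (3 higher, 6 lower), 0 with an estimated correlation. The count was 141 without B1 replicate 1, 140 without B1 replicate 2, 1599 without a filter on low counts and 1579 with offsets for GC content and length.

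B1 and F5 shared 267 genes higher and 301 lower than in WT, against 77.8 and 85.0 for independent calls, and 80 genes differed from WT in opposite directions. These comparisons use the same WT libraries, which by itself makes them alike. In 10 simulations in which clones differed but genotypes did not, a mean of 803 genes was shared higher and 758 lower, against 304 and 268 for independent calls. Sharing more than independent calls is therefore expected without an effect of genotype. These simulations gave every clone the same spread, so their counts are not those of F5 and B1. With separate WT clones as the references the excess depended on the pairing. F5 against E5 and B1 against G5 shared 292 higher and 336 lower genes (101 and 168 for independent calls), with 399 opposite. F5 against G5 and B1 against E5 shared 216 and 225 (212 and 173 for independent calls), with 612 opposite. In both pairings the opposite genes outnumbered those shared higher and those shared lower, each taken alone. For opposite genes no value for independent calls was computed, so an excess of shared genes does not by itself show agreement. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.314 with the same WT libraries, against a mean of 0.327 in these simulations (0.294 to 0.345). The covariance was 0.115, against 0.131 (0.119 to 0.138). Neither value lay above its simulated range. Both measures depend on how far each clone lies from WT, and the simulations gave every clone the same spread. They therefore cannot decide whether B1 and F5 were more alike than clones without an effect of genotype. In the pairings with separate WT clones the correlation was -0.116 and 0.0623 and the covariance -0.0634 and 0.0296. When the WT libraries were divided by replicate number the correlation was 0.286 and the covariance 0.102.

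The clones of a genotype differed from each other about as much as clones of different genotypes, with median SDs of log2 differences between libraries of 0.637 and 0.608. NNAT, an imprinted gene of neuronal differentiation, had 0 CPM in the WT clone E5 and 310 in G5, 361 in B1 and 297 in F5, at least 1486-fold lower in E5 at a floor of 3 counts per library. CAT, the peroxisomal catalase, had 0 CPM in E5 and 19.2 in G5, and C17orf51 had 0 and 64.3. TRIM4, a ubiquitin ligase, and the RNA AC010615.2 had 0 and 0.0336 CPM in E5 and 11.1 and 47.0 in G5. The fits therefore placed NNAT, CAT and C17orf51 among the highest of F5 against WT, and NNAT, TRIM4 and AC010615.2 among those of B1 against WT. In G5 the lowest were HSD17B7P2 (0.145 CPM, against 11.8 in E5), AL117339.5 (0.235, against 7.44) and TFAP2B, which was high in E5 replicate 2 only. In all, 3084 genes were higher and 2804 lower in G5 than in E5 (5888, 32.3%), 2828 without G5 replicate 2 and 3242 with offsets for GC content and length. The 4 lists that passed were the Notch and ventral lists above and G1/S cell cycle, higher in G5 (camera adjusted p = 0.00175), and p53 targets, lower in G5 (0.0133). All 4 had adjusted p = 0.809 with an estimated correlation. With offsets for GC content and length 9 lists passed. The Notch list did not (0.451), and 6 others did: hem and choroid plexus (0.0337), astroglia (0.0337), G2/M (0.00539), WNT targets (0.0346), mitochondrially encoded proteins (0.00972) and the zinc finger cluster (0.00551). The cluster was higher in G5 with the offsets, and without them it did not pass (0.455).

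Between the clones labelled KO, 2628 genes were higher and 2555 lower in F5 than in B1 (5183, 28.4%), and 2244 and 1704 (3948) with offsets for GC content and length. ZNF558, ZNF559 and C17orf51, which had 0 to 0.168 CPM in B1, had 53.9, 59.4 and 46.0 in F5. The lowest in F5 were RNU1-1, a spliceosomal RNA (1.53 CPM, against 308 and 10.5 in the B1 libraries), ABCA4, a retinal transporter (0.154, against 12.7), and DCT, a melanin enzyme (0.378, against 16.8). The hem (camera adjusted p = 9.78e-08), WNT target (6.20e-08), p53 (1.01e-06) and immediate early lists (5.78e-06) were lower in F5 and the zinc finger cluster higher (6.20e-08). In all 16 lists passed, 0 of them with an estimated correlation (smallest adjusted p = 0.0701). The count of genes was 3321 and 2741 without F5 replicate 1 and 2, and 2217 and 2450 without B1 replicate 1 and 2.

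**Figure D3:**
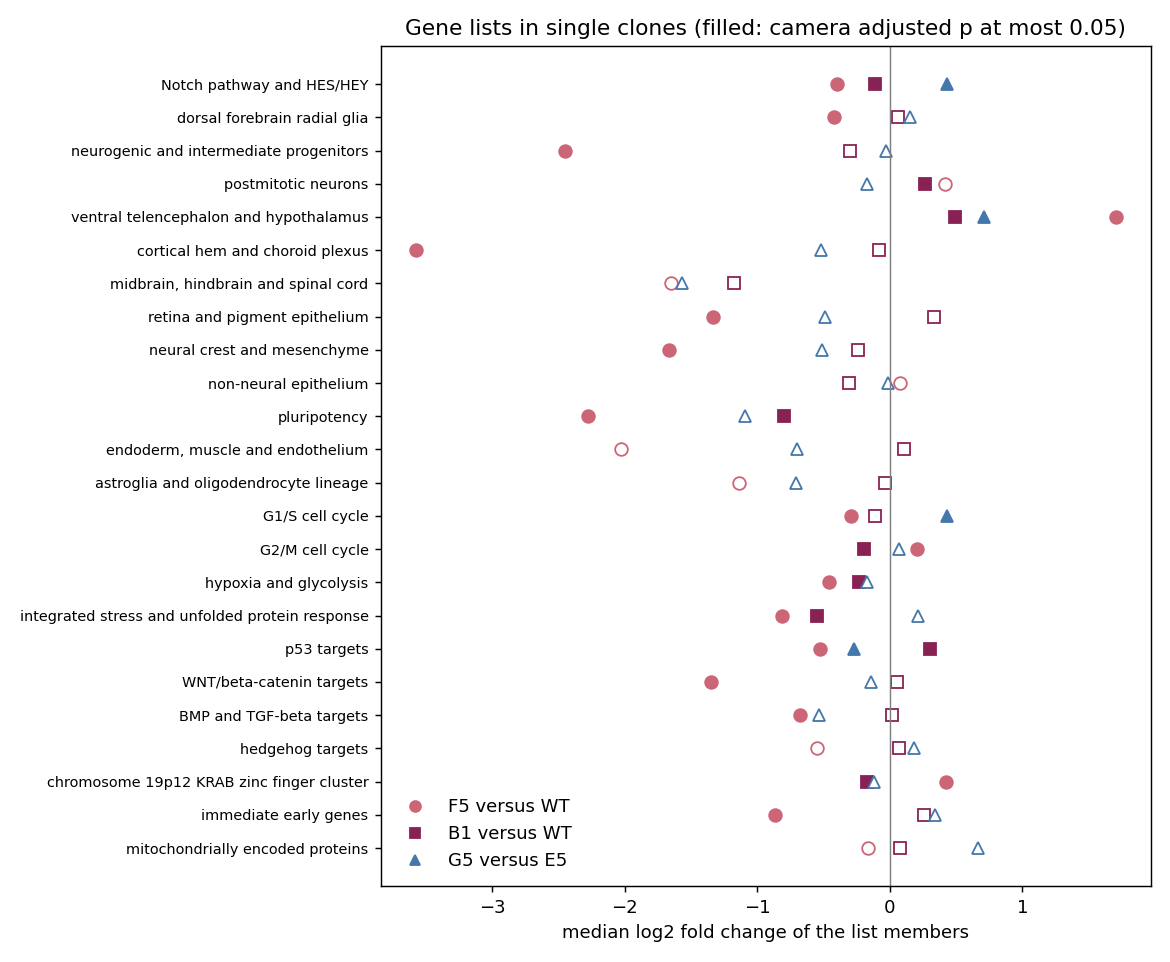
Median log2 fold change of the tested members of each of the 24 gene lists (horizontal axis) for F5 against WT (circles), B1 against WT (squares) and the WT clones G5 against E5 (triangles), filled where the camera adjusted p with the preset correlation is at most 0.05. The stress response list lies at -0.81 in F5 and -0.55 in B1 and at 0.21 between the WT clones, while the hem and choroid plexus list lies at -3.58 in F5 and -0.08 in B1.

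Libraries of a clone were nearer to each other than libraries of different WT and KO clones. The SD of the log2 differences over 14809 genes was 0.237 to 0.374 between libraries of a clone, 0.581 to 0.698 between clones of the same genotype and 0.461 to 0.822 between a WT and a KO clone. Genes of chromosome 12 stood apart in the WT clone G5, where they had a median log2 difference of 0.51 from the other clones, a fold of 1.42, over 803 genes. The median was 0.52 in G5 replicate 1 and 0.51 in replicate 2, and all other pairs of clone and chromosome lay between -0.19 and 0.20. Of the genes named here, DDIT3, LUM, PMEL, MDM2, NEUROD4, NR4A1, MARS and CDK2 lie on chromosome 12. Without the genes of chromosome 12, 1 gene passed KO against WT, SLC5A12, and 10 lists.

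**Figure D4:**
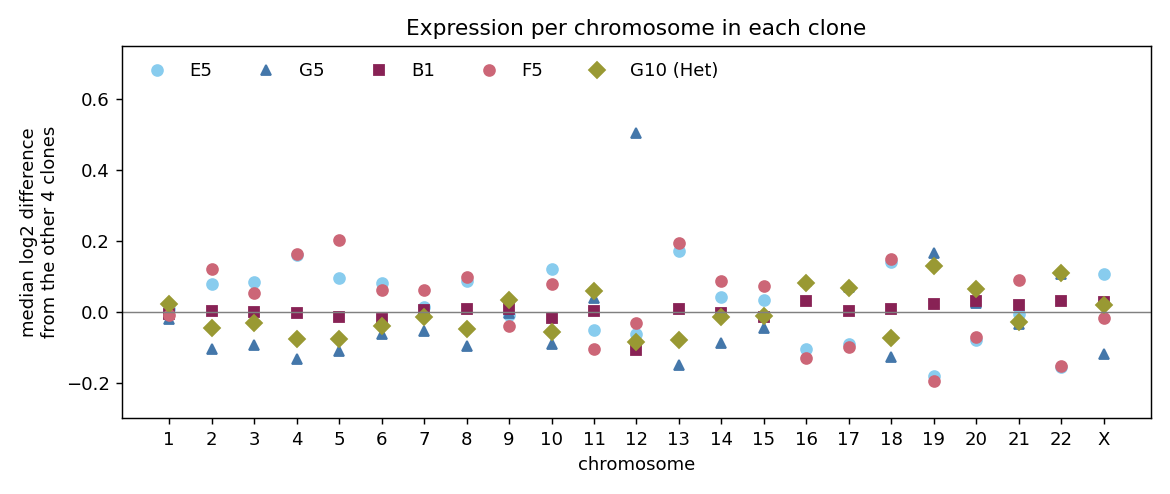
Median log2 difference of each clone from the other 4 clones (vertical axis) over the genes of each chromosome (horizontal axis), with symbols and colours for the clones. Chromosome 12 in the WT clone G5 lies at 0.51, and all other points lie between -0.19 and 0.20.

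The Het library has no replicate, so it was compared without a test. Its HES1 level, 111 CPM, lay within the WT range, and its ZNF675 level, 32.9 CPM, just above the highest WT library (32.1). For SLC5A12 it lay in the direction of the libraries labelled KO, with a log2 difference from WT of -1.87. Over all genes it was nearest to B1, with SDs of log2 differences of 0.280 and 0.300 to the B1 libraries, within the range between libraries of a clone. Whether G10 arose independently of B1 is not stated, so its SLC5A12 value is not independent evidence on the Het genotype.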

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

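All tests of explanations in this part were chosen after the results were seen.

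The clones labelled KO differed from each other. The test of F5 against B1 passed for 29 of the 50 genes named for KO against WT or as members of lists. The genes named for the comparisons of single clones are not counted here. The log2 differences of F5 from B1 were 0.38 for ZNF675, -2.03 for HES1, 0.89 for HES5, -0.93 for MFNG and -0.58 for NRARP. Among neuronal and ventral genes they were 0.79 for DCX, 0.37 for INA, 1.17 for GAD2, 1.51 for DLX1, 1.40 for GSX2 and 1.40 for DLX6. Among neurogenic and progenitor genes they were -1.64 for NEUROD1, -2.05 for NEUROD4, -0.38 for SOX2, -0.79 for NES, -2.29 for LIN28A and -0.39 for DNMT3B. Among genes of the hem, eye and WNT pathway they were -2.64 for RSPO3, -4.61 for WNT8B, -2.74 for WNT5A, -2.06 for OTX1, -1.47 for ZNRF3 and -0.59 for AXIN2. The others were -0.64 for ALDOC, -1.24 for TNFRSF10B, -0.99 for IER2, -0.55 for NR4A1, 2.24 for OLIG1 and 1.01 for PTCH1. With offsets for GC content and length 7 of the 29 did not pass. Their log2 differences were then 0.06 for ZNF675 (adjusted p = 0.690), -0.32 for ALDOC (0.250), -0.56 for MFNG (0.113), -0.15 for NRARP (0.326), -0.16 for DNMT3B (0.359), -0.21 for SOX2 (0.112) and -0.22 for NR4A1 (0.300).

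Of the lists, 16 differed between F5 and B1 with the preset correlation of camera. The adjusted p was 0.0250 for Notch, 0.00226 for radial glia, 0.00127 for neurogenic progenitors, 0.00199 for ventral telencephalon, 9.78e-08 for hem and choroid plexus, 0.000810 for retina, 0.00687 for neural crest, 0.0352 for pluripotency and 0.0413 for endoderm, muscle and endothelium. It was 0.0496 for G1/S, 0.000118 for G2/M, 1.01e-06 for p53 targets, 6.20e-08 for WNT targets, 0.0106 for BMP and TGF-beta targets, 6.20e-08 for the zinc finger cluster and 5.78e-06 for immediate early genes. With offsets for GC content and length 14 of the 16 passed, and Notch (0.219) and G1/S (0.113) did not. With an estimated correlation 0 lists passed. The count of genes that differed was 5183.

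A WT library lay far from the other 3 for 6 genes, of 100 groups of libraries looked at for the 50 genes, where chance gives about 1 in 20. The gap to the nearest library over the range was 0.965 for SLC5A12, 0.864 for NHLH2, 0.966 for WNT2B, 0.979 for TFAP2B, 0.984 for TFAP2A and 0.890 for SOX2.

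ZNF675 RNA was higher in the libraries labelled KO, 55.7 against 28.4 CPM. A trend with GC content or length is argued against as the whole cause, since the log2 fold change was 0.88 with offsets for both, against 0.97 without. Reads of related zinc finger genes cannot be told apart from those of ZNF675: the median log2 difference of the 23 other tested members of its cluster between B1 and WT was -0.18, with 0 higher, but in F5 14 were higher, and how reads mapping to several genes were counted is not known. Variation between clones stays open too, because the exact permutation p of 0.333 is the smallest the 4 clone means allow. A response of the edited gene to its own loss may also raise its RNA, and it was not tested.

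Chromosome 12 genes were higher in the WT clone G5, by a median log2 of 0.51. A GC or length trend is argued against by a median of 0.53 with offsets for both, and a few strongly changed genes by the 75.2% of its genes that were highest in G5 among the 5 clones, where chance gives 20% and the highest other pair of clone and chromosome had 46.4%. An extra copy of the chromosome in G5 may be the cause: the lowest of 20 windows of 40 genes had a median of 0.28 and the highest 0.79, on either side of the 0.58 expected from 3 copies in place of 2. RNA alone cannot show copy number, and no DNA data were at hand.

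The stress response list was lower in both clones labelled KO with camera at its preset correlation. With an estimated correlation it did not pass for KO against WT (adjusted p = 0.106), in F5 (0.281) or in B1 (0.445). At the preset correlation a GC or length trend is argued against by an adjusted p of 3.20e-11 with offsets for both. The higher expression of chromosome 12 genes in G5 is argued against by 1.18e-07 without that clone. Variation between clones cannot be told apart from the genotype: the partings of the 4 clones that mix genotypes had adjusted p of 0.696 and 0.990 for this list, but there are only 3 partings in all. An effect of the genotype is consistent with the values and could not be tested apart from the clones.

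Chance cannot be excluded for the counts of KO against WT. Of the 35 splits of the 8 libraries into equal groups, 3 gave as many genes as the real 2, the real split included, and the highest other gave 1278. The other 2 were the splits that keep clones whole and mix genotypes, F5 with E5 (1278 genes) and F5 with G5 (136). This points to the clones as the main structure of these libraries. Splits that divide clones put the clone differences into the spread within groups, and each gave 0 genes. They are therefore no measure of how rare the real split is. Among the 3 splits that keep clones whole, KO against WT had the fewest genes. Within the spread between pools F5 with E5 had 7255 genes, F5 with G5 3055 and KO against WT 4432. For the lists 13 of the 35 splits gave as many as the real 11, and the highest other gave 19.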

How the results depend on the processing

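The offsets for GC content and length and the removal of chromosome 12 were chosen after seeing the data, and the other alternatives were set beforehand. KO against WT, with 2 genes, gave 614 with the DESeq2 Wald test, 209 without a filter, 201 with the GC and length offsets and 1 without the genes of chromosome 12. It gave 0 with limma-voom (2559 genes at an unadjusted p under 0.05), 0 on counts summed per clone (674), 0 with clone as a random block (1011), 0 with the replicate number as a block (2156) and 0 with offsets on clone sums (1053). Of the 201 genes all had the same direction without offsets and 195 had clone means apart, against 28.3% of all genes tested. The 201 were chosen on the same libraries, so neither value is separate evidence for them. Leaving out a library gave 0 to 1, and leaving out a clone gave 482 (E5), 11 (G5), 1738 (B1) or 4 (F5). The replicate block is a value only, since replicate numbers do not pair the libraries: correlations of their deviations across genes were -0.16 to 0.09. Without a clone a genotype holds a single clone, so its spread between clones leaves the test; for the other settings the cause was not tested.

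F5 against WT gave 4441 to 7172 genes and F5 against B1 2217 to 5664 when a library was left out. B1 against WT gave 140 to 1090, 1599 without a filter and 1579 with the offsets, and G5 against E5 gave 2828 to 5898 and 3242 with the offsets; the cause was not tested. Where a clone kept 1 library, it was assumed to vary like the other clones. With the replicate block they gave 6638, 4795, 772 and 5503.

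The lists, 11 with the preset correlation, gave 0 with an estimated correlation and 2 with fry, 11 with camera on ranks, 9 to 17 without a library, 6 without clone E5 and 18 without clone B1. Without clone F5, lists changed direction: G2/M (adjusted p = 0.00511, lower), p53 targets (0.00511, higher), WNT targets (0.490, higher), the zinc finger cluster (0.0287, lower) and immediate early genes (0.0350, higher); the cause was not tested. The stress list kept its direction under every alternative run, and its adjusted p ranged from 8.88e-12 to 0.106.

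ZNF675 was higher in the libraries labelled KO under every alternative, with a log2 fold change of 0.87 to 1.05 without a library. It passed the threshold with DESeq2 (0.96), without a filter (0.96), without clone E5 (1.11), without clone B1 (1.14) and with the offsets (0.88). HES1 passed without clone B1 (-2.29) and was -1.27 to -0.63 without a library; the cause was not tested. The Het library lay 2.20 log2 units from WT in the direction of the KO libraries as the median of the 2 called genes, also with DESeq2 size factors, and whether its clone is independent of B1 is not known. Genes chosen on part of the WT libraries gave no value, since 0 genes passed there. Genes under about 0.2 CPM cannot be told from 0 at this depth.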

Other observations

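The tests in this part were chosen after the data were seen, and no explanation was tested here.

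A group of 16 genes was off (under 0.2 CPM) in some clones and on (at least 5 CPM) in the rest. They were chosen after their values were seen. The count was 10 in the WT clone E5, 3 in the WT clone G5, 6 in B1, 3 in F5 and 7 in the Het clone. All 6 genes off in B1 were also off in the Het clone, and 5 of the 10 off in E5, while 0 of those off in G5 or F5 were. ZNF558 had 1 count and ZNF559 0 counts in the Het library, as in B1. ZNF596, a zinc finger gene on chromosome 8, had 0 CPM in G5 and F5 and 20.3 in E5, at least 58.6-fold lower in F5 and at least 64.1-fold lower in G5 than in the lowest clone that expressed it. LRRC61 and ZBED6CL, neighbours on chromosome 7, were at 0 CPM in E5 and B1 and had 27.7 and 9.39 CPM in G5.

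In a principal component analysis of the 1000 most variable genes, the first component (57.8% of the variance) placed the F5 libraries at 52.2 and 38.5 and all others below 0. The second component (17.6%) placed G5 at -21.3 and -21.5 and E5 at 17.7 and 20.8. The Het and B1 libraries lay together on the third (13.3%), at -15.7 for Het and -16.6 and -15.5 for B1.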
